A study of Mus musculus with 6 samples.

How the data were processed

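Gene expression was measured by RNA sequencing in 6 libraries that the labels describe as primary mouse chondrocytes from cartilage. Of these, 3 were exposed to PMUC, a treatment the labels name only by this abbreviation, and 3 received PBS as the control. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

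Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. They were sequenced as 150 bp paired-end reads on a NovaSeq 6000 instrument. Reads were trimmed with fastp 0.23.4, and aligned with HISAT2 2.2.1, and gene counts were made with HTSeq-count 0.13.5, per the labels' protocols. The submitters' processing notes also name SAMtools, DESeq2 and R 3.2.0. Whether counting used strand is not given in the sources used here, so it is unknown whether reads of overlapping genes and antisense partners were told apart. The deposited count table holds whole-number counts without normalization for 19931 genes, each with at least 1 count in some library. The deposited FPKM values were made by the authors from those counts: each equals the count divided by 1 length per gene and by the library's total, with a largest relative deviation of 1.29e-13. The implied gene lengths ran from 154 to 106374 bases, with a median of 3080. All 6 count columns and all 6 FPKM columns were matched to samples by name. A pair of small summary sheets was not used here.

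The sources disagree on the organism and build. The labels name mouse cells, while the labels' protocols name the human build GRCh38/hg38 for alignment. In the deposited count table, 0 gene identifiers matched the mouse gene table used here, 7206 of the 7206 rows with a pathway carried rat pathway codes, and 0 carried mouse or human codes. Also, 228 symbols begin with RGD and digits and 37 with RT1, as rat symbols do, so the gene annotation of the tables is that of rat. Of the symbols, 14677 also exist as mouse symbols. The total count per library, from 34292189 to 40713828, lay near the number of clean reads that the labels' protocols state. Most reads were therefore probably counted on rat genes, which leans towards rat cells. The stated read number is approximate, since some totals exceed it. How mouse reads would fare with a rat annotation was not tested, so the organism of the cells could not be settled from the tables. Genes are given by the symbols and identifiers in the tables, without coordinates, and a check of GC content was not made.

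The total count per library ran from 34292189 to 40713828. A count of 0 allows up to 3 counts, which is 0.0737 to 0.0875 CPM (counts scaled to a common library total) depending on the library. This limit covers counting error only, since the reads carried no molecular identifiers that were used here.

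Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F-test, TMM factors and its default expression filter, with group as the only term. Benjamini-Hochberg adjusted p under 0.05 over all tested genes was the threshold, and changes of more than 2-fold were also counted. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-normalised CPM, as mean ± SD. On simulated counts for 13614 genes of this PMUC against PBS comparison, with 200 genes changed, 68.7% of genes changed 1.3-fold, 77.6% of those changed 1.5-fold and 87.9% of those changed 2-fold were recovered. In that simulation 6 unchanged genes passed, and with no gene changed 0 passed. Genes were drawn independently, with a spread set by expression level alone and libraries that differed only in total. The real libraries differ in more ways, so these shares need not hold for them.

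In all, 28 gene lists were fixed before the data were examined. They cover cartilage matrix, matrix-degrading enzymes, pyroptosis, inflammatory cytokines, hypertrophy, dedifferentiation, extracellular vesicles, mechanosensing, hyaluronan, oxidative stress, autophagy, the unfolded protein response, heat shock, glycolysis, oxidative phosphorylation, lipid synthesis, the cell cycle, senescence, interferon, TGF-beta and 8 sets of markers of other cell types. List symbols were matched without regard to case and through older mouse symbols. Each list with at least 3 tested members was compared with the other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 27 lists. Camera with an estimated correlation and fry were run beside it. Terms in the deposited annotation columns were tested by a one-sided Fisher's exact test against the tested genes that carry any term of the same source, for terms with 10 to 500 genes. Principal components used the 500 most variable genes.

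The genes named were set by rule before the data were examined. The 8 largest rises and 8 largest falls came from genes past the threshold with a named symbol, a mean count of at least 100 and groups that did not overlap. To these were added the 4 smallest p in each direction, 19 genes tied to the study's topic whatever their result, and up to 4 called members per list, or 2 where none passed. Some genes that the rule names are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Akr1b8 with Akr1b10, and Gsta5 with its relatives, belong to families of near-identical genes, so how reads were split among them is uncertain.

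The alternatives set in advance were RLE and upper-quartile factors, no count filter, CPM of at least 5 in 3 libraries, DESeq2 1.42.0, limma voom, and limma on log2(FPKM + 1), for genes at an FPKM of 1 or more in 3 libraries. Also set in advance were log2(FPKM + 0.1), log2(FPKM + 1) without that filter, the replicate number as a block, named symbols only, and leaving out each of the 6 libraries in turn. A fit with each library's trend with gene length removed was added after the data were seen.

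For the closing section, 20 further targets of NRF2, 10 transcripts abundant in leukocytes and 14 members of the oxidative stress list without close relatives were listed after the main comparison had been seen. Predictions for tests on them were written beforehand or afterwards, as stated there. The sum of leukocyte transcripts without Cd14 was added after Cd14 was seen to dominate it.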

Results

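The libraries compared cells labelled chondrocytes that were exposed to PMUC with others given PBS, 3 libraries in each group. The series title places PMUC in work on an artificial synovial fluid, anti-pyroptotic extracellular vesicles and osteoarthritis, and the design asks which genes differ in expression between the groups. Total counts were 39743574, 34292189 and 40713828 in PBS replicates 1, 2 and 3, and 36263009, 35320694 and 38656372 in PMUC replicates 1, 2 and 3. The labels name mouse cells, but the gene annotation in the tables is that of rat (rat pathway codes for 7206 of the 7206 genes with a pathway), so symbols are given as the tables hold them. Fn1, which encodes fibronectin, was the gene with the most counts in 5 of the 6 libraries, at 1.77% to 2.10% of counts.

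Of the genes tested, 17 of 26 oxidative stress genes and NRF2 targets, 9 of 25 genes of glycolysis and hypoxia and 10 of 34 inflammatory cytokine genes and NF-kB targets were higher in PMUC than in PBS. Camera gave these lists adjusted p of 7.55e-14, 4.96e-06 and 0.000939, and of 0.268, 0.813 and 0.813 with an estimated correlation. By fry their adjusted p was 0.0054, 0.147 and 0.147, and of all 27 lists only 1 passed. Among the genes that were lower were Psat1, of serine synthesis, Asns, of asparagine synthesis, and Gsdmd, while the pyroptosis list that holds Gsdmd went both ways, with 4 members higher and 3 lower. Nqo1, a quinone reductase that NRF2 induces, rose 2.86-fold, and Gsdmd, the pore-forming gasdermin, fell to 0.776 of its level in PBS. Of 13614 genes tested, 443 were higher and 510 were lower in PMUC at an edgeR adjusted p under 0.05. Most of the differences were small: 76.3% of these 953 genes differed by less than 1.5-fold, and 30 rose and 28 fell by more than 2-fold. The median fold was 1.28 for the genes that rose and 1.33, as PBS over PMUC, for those that fell. Higher genes made up 46.5% of the calls, against 30.8% (265 higher, 596 lower) with limma on log2(FPKM + 1). With upper-quartile factors in the same edgeR test they made up 37.7% (378 higher, 624 lower), and without PBS replicate 3 59.6%. In 28.6% of tested genes the groups did not overlap, where chance gives 10%. The number of calls depended on the libraries: it was 1829 without PBS replicate 1, 344 without PBS replicate 3, and 397, 421 and 289 without PMUC replicates 1, 2 and 3. The 28 falls of more than 2-fold became 58, 10, 15 and 11 without PBS replicate 1, PBS replicate 3, PMUC replicate 2 and PMUC replicate 3, and the 30 rises became 47 without PBS replicate 1. Of the 19 gene lists with a called member, 18 had a number of rises or falls that moved by over 1.5 times without some library. Of the 73 named genes past the threshold, 40 lost the call with log2(FPKM + 1) and no filter, 7 and 8 with log2(FPKM + 1) and log2(FPKM + 0.1), and 22, 20, 18 and 27 without PBS replicate 3 and PMUC replicates 1, 2 and 3.

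**Figure D1:**
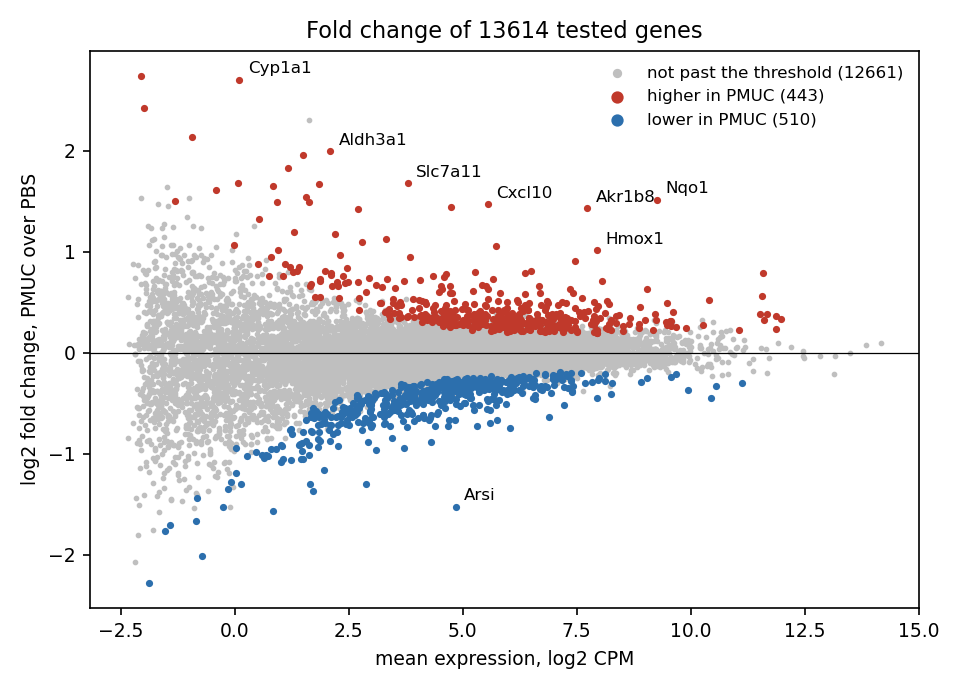
Log2 fold change of PMUC over PBS (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 13614 tested genes. Red points are the 443 genes higher and blue points the 510 genes lower in PMUC at an edgeR adjusted p under 0.05, and Nqo1 and Akr1b8 stand out among abundant genes.

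The largest rises among called genes with a mean count of at least 100 included several enzymes that clear aldehydes, quinones and other reactive compounds. Aldh3a1, an aldehyde dehydrogenase, rose 3.99-fold (log2 fold change 1.995, SE 0.18, edgeR adjusted p = 6.18e-05), from 1.70 ± 0.41 to 6.85 ± 0.72 CPM (SD, n = 3 each). Adh7, an alcohol dehydrogenase, rose 3.88-fold, Slc7a11, the cystine importer that supplies glutathione synthesis, 3.21-fold, and Akr1b10, an aldo-keto reductase, 3.19-fold. Ddit4l, an inhibitor of mTOR signalling, rose 2.90-fold, Nqo1, a quinone reductase, 2.86-fold, Gsta5, a glutathione S-transferase, 2.81-fold, and the chemokine gene Cxcl10 2.78-fold. The smallest p-values among genes that rose belonged to Akr1b8 (edgeR adjusted p = 1.26e-07), Nqo1 (edgeR adjusted p = 3.22e-07), Ptgr1 (edgeR adjusted p = 1.04e-06) and Txnrd1 (edgeR adjusted p = 4.60e-06). Akr1b8 rose from 115 ± 6.10 to 309 ± 16.9 CPM and Ptgr1, a reductase of prostaglandins and leukotrienes, from 14.5 ± 1.58 to 39.2 ± 1.12 CPM. The tables list Nqo1 under the identifier 24314, Akr1b8 under 286921, Ptgr1 under 192227 and Txnrd1 under 58819. Akr1b8, Akr1b10 and Gsta5 have near-identical relatives, so their counts are uncertain.

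Among called genes with a mean count of at least 100, the largest falls were in genes of varied function. Arsi, which encodes a sulfatase, fell from 42.8 ± 8.33 to 14.9 ± 2.38 CPM, a level 2.87-fold lower (log2 fold change -1.52, SE 0.14, edgeR adjusted p = 6.54e-05). Kcnh2, a potassium channel gene, was 2.58-fold lower, Car3, a carbonic anhydrase gene, 2.47-fold, Mycbpap 2.46-fold, Clcn4, a chloride-proton exchanger gene, 2.24-fold, Hacd4 2.07-fold, Acss3 2.07-fold and Drd1, a dopamine receptor gene, 2.01-fold. The smallest p-values among genes that fell belonged to Aldh1l2, a mitochondrial folate enzyme (25.8 ± 1.10 to 13.98 ± 0.82 CPM, edgeR adjusted p = 6.18e-05), Arsi, Kazald1 (edgeR adjusted p = 0.000214) and B3gnt9 (edgeR adjusted p = 0.000364). The calls of Hacd4 and Drd1 depended on single libraries: the edgeR adjusted p of Hacd4 was 0.0535 without PMUC replicate 3, and that of Drd1 was 0.0856, 0.0646 and 0.0527 without PBS replicate 3, PMUC replicate 1 and PMUC replicate 2.

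With all 6 libraries, oxidative stress genes and targets of NRF2, the transcription factor that induces antioxidant enzymes, had the smallest camera p and the largest number of calls of the lists tested. Of 26 members tested, 17 rose, 0 fell and 9 did not pass the edgeR threshold, and 21 rose and 1 fell when adjusted over the list alone. Nqo1 went from 319 ± 29.0 to 914 ± 68.5 CPM, and Hmox1, which breaks down heme, from 162 ± 25.1 to 328 ± 8.80 CPM. Txnrd1, a thioredoxin reductase, went from 122 ± 7.68 to 230 ± 4.83 CPM, and Slc7a11 from 6.57 ± 2.21 to 21.2 ± 2.05 CPM. All 3 PMUC libraries lay above all 3 PBS libraries for these 4 genes. The median log2 fold change of the list was 0.41, and camera gave an adjusted p of 7.55e-14. With an estimated correlation between genes the camera adjusted p was 0.268, while fry, which asks only whether the members move one way on balance, gave an adjusted p of 0.00543.

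**Figure D2:**
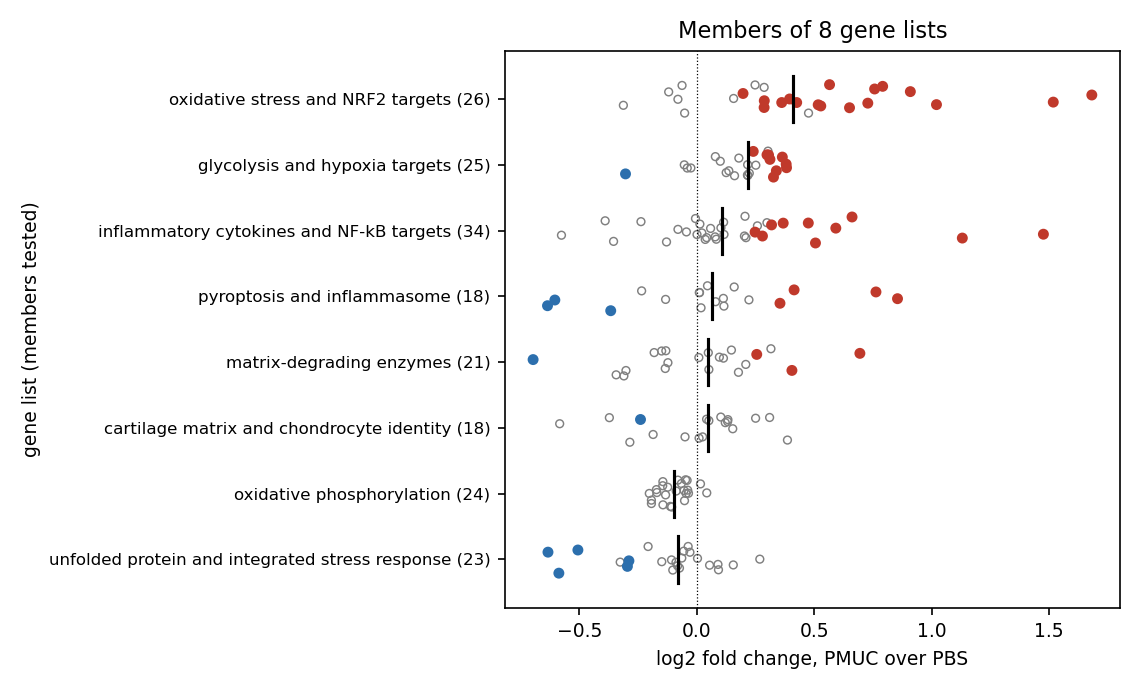
Log2 fold change of PMUC over PBS (horizontal axis) for each tested member of 8 gene lists (rows, with the number of tested members). Red and blue points passed the edgeR threshold upward and downward, open points did not, and black bars are list medians, which run from 0.41 for the oxidative stress list to -0.10 for oxidative phosphorylation.

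Genes of glycolysis and of the response to hypoxia shifted upward by camera with the preset correlation, but not by the other list tests. Of 25 members tested, 9 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median log2 fold change of 0.22 and a camera adjusted p of 4.96e-06. The correlation estimated for this list was 0.59, with which the camera adjusted p was 0.813, and fry gave an adjusted p of 0.147. Pkm, the last enzyme of glycolysis, rose from 2839 ± 157 to 3699 ± 7.10 CPM, Gapdh from 3254 ± 143 to 4188 ± 161 CPM, and Ldha, which makes lactate, and Pgk1 rose by 0.34 and 0.38 on the log2 scale. Egln3, an oxygen-sensing hydroxylase gene that hypoxia induces, was the member that fell (log2 fold change -0.30, edgeR adjusted p = 0.0377), and is named because it was the only such member, after its value was seen. With any 1 library left out except PBS replicate 2, 0 members fell. Without PMUC replicate 3, the edgeR adjusted p of Ldha was 0.0647 and that of Pgk1 was 0.0628, and without PBS replicate 3 that of Pgk1 was 0.0552. Between 2 and 4 members rose without PBS replicate 3 or any 1 of the PMUC libraries, and 17 rose without PBS replicate 1. The list of 24 tested oxidative phosphorylation genes had a camera adjusted p of 0.0491 in the downward direction, and of 0.813 with an estimated correlation. Its fry adjusted p was 0.4645. It had 0 members past the edgeR threshold (0 also when adjusted over the list alone), 2 members above 0 and a median log2 fold change of -0.10. Ndufs1, a subunit gene of complex I, had a log2 fold change of -0.17 (SE 0.06, edgeR adjusted p = 0.103). By camera its adjusted p was 0.661 without PBS replicate 2, 0.357 without PMUC replicate 1, 0.0772 without PMUC replicate 3, 0.0529 with named symbols only and 0.715 with the trend with gene length removed.

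Inflammatory cytokine genes and targets of NF-kB shifted upward by camera with the preset correlation. Of 34 members tested, 10 rose and 0 fell (13 and 2 when adjusted over the list alone), with a median log2 fold change of 0.11 and a camera adjusted p of 0.000939. Adjusted by camera with an estimated correlation, p was 0.813, and the fry adjusted p was 0.147. Cxcl10, a chemokine that recruits T cells, rose from 24.9 ± 2.93 to 69.4 ± 8.91 CPM (edgeR adjusted p = 5.71e-06), Ccl5 from 6.22 ± 1.72 to 13.7 ± 0.86 CPM, Ccl20 from 194 ± 12.8 to 276 ± 17.6 CPM and Cxcl2 from 69.1 ± 8.18 to 96.0 ± 6.76 CPM. Il6 (log2 fold change -0.24, edgeR adjusted p = 0.113) and Ptgs2 (0.26, edgeR adjusted p = 0.0833), the gene of cyclooxygenase-2, did not pass. The adjusted p of Ptgs2 was 0.00482 without PBS replicate 1, 0.00202 with no count filter, 0.0246 (DESeq2) and 0.0313 with the trend with gene length removed, and that of Il6, downward, was 0.0459 and 0.0464 with log2(FPKM + 1) and log2(FPKM + 0.1). The number of list members that rose was 5 without PBS replicate 3 and 4 and 6 without PMUC replicates 1 and 3.

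Among 22 tested interferon-stimulated genes, 2 rose and 2 fell (3 and 2 when adjusted over the list alone). Isg15, a ubiquitin-like protein gene, rose from 3.51 ± 0.55 to 9.49 ± 0.79 CPM, and Usp18, which removes it from proteins, rose by 0.60 on the log2 scale. Psmb8, an immunoproteasome subunit gene, was lower by a log2 fold change of -0.52 and Irf7, an interferon regulatory factor gene, by -0.92. The list's median was -0.11, its mean was 0.04, and its camera adjusted p was 0.701. The edgeR adjusted p of Usp18 was 0.0597 and 0.0747 without PBS replicate 3 and PMUC replicate 3, and that of Irf7 was 0.0597, 0.0650 and 0.0619 without PBS replicate 3, PMUC replicate 1 and PMUC replicate 3.

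Pyroptosis is a lytic form of cell death in which inflammasomes activate caspases and caspases cleave gasdermins. Of 18 tested genes of this pathway, 4 rose and 3 fell, and 5 rose and 4 fell when adjusted over the list alone. Gsdmd, the pore-forming gasdermin, fell from 49.8 ± 0.25 to 38.7 ± 0.74 CPM (log2 fold change -0.37, SE 0.06, edgeR adjusted p = 0.00345). Casp4, a caspase that cleaves it, fell from 11.8 ± 1.53 to 7.57 ± 0.44 CPM, and Pycard, the inflammasome adaptor, from 6.84 ± 0.35 to 4.50 ± 0.47 CPM. In the other direction, Gbp5, a guanylate-binding protein gene, rose from 15.1 ± 2.80 to 25.7 ± 2.75 CPM, and 3 more members rose. Of these, Il1b went from 1.90 ± 0.36 to 3.43 ± 0.98 CPM (edgeR adjusted p = 0.0454), and Gbp2 and Il1a are named after their values were seen. All 3 PMUC libraries lay below all 3 PBS libraries for Gsdmd, Casp4 and Pycard. Nlrp3 had a log2 fold change of 0.16 (SE 0.09, edgeR adjusted p = 0.294), and Casp1 was detected with 0 to 13 counts per library (0.08, SE 0.74, edgeR adjusted p = 0.961), a level at which a difference of this size was not detectable. Gsdme had 1 to 7 counts and Il18 0 to 5 counts per library, too few to be tested. As a list these genes did not shift (camera adjusted p = 0.699), and fry's test for change in either direction gave an adjusted p of 0.000196, a test that 20 of the 27 lists passed. The edgeR adjusted p of Pycard was 0.0830 without PMUC replicate 3, and that of Il1b was 0.0548, 0.162, 0.152 and 0.158 without PBS replicates 1 and 3 and PMUC replicates 1 and 2. With limma voom, log2(FPKM + 1), log2(FPKM + 0.1), and log2(FPKM + 1) with no filter, the adjusted p of Il1b was 0.0676, 0.0552, 0.0548 and 0.211. The number of members that rose was 1 without PBS replicate 3, PMUC replicate 1 or PMUC replicate 2 and 2 without PBS replicate 2 or PMUC replicate 3.

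Genes of matrix-degrading enzymes went both ways, with 3 of 21 tested members higher and 1 lower in PMUC (4 and 3 when adjusted over the list alone). Mmp3, the stromelysin gene, went from 673 ± 56.0 to 891 ± 163 CPM (edgeR adjusted p = 0.0364), and Mmp10 and the urokinase gene Plau also rose, by 0.69 and 0.26 on the log2 scale. Adamts4, an aggrecanase gene, fell from 8.66 ± 0.42 to 5.34 ± 0.81 CPM (log2 fold change -0.70, SE 0.13, edgeR adjusted p = 0.00685). The other aggrecanase gene Adamts5 (-0.31, SE 0.12, edgeR adjusted p = 0.145) and the collagenase gene Mmp13 (0.18, SE 0.11, edgeR adjusted p = 0.381) did not pass. The list had a camera adjusted p of 0.939, and its direction by fry was opposite to that by camera. Without PBS replicate 3, PMUC replicate 1 and PMUC replicate 3, the edgeR adjusted p of Mmp3 was 0.129, 0.126 and 0.0636. That of Mmp10 was 0.0710 and 0.0572 without PMUC replicates 1 and 3, and that of Plau was 0.0837, 0.115 and 0.0945 without PMUC replicates 1, 2 and 3. The number that rose was 0 without PMUC replicates 1 or 3, and the number that fell was 2 without PBS replicates 1 or 2, with upper-quartile factors, with no count filter, with DESeq2, with the trend with gene length removed and in the filtered FPKM fits. In the FPKM fit with no filter 0 passed.

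**Figure D3:**
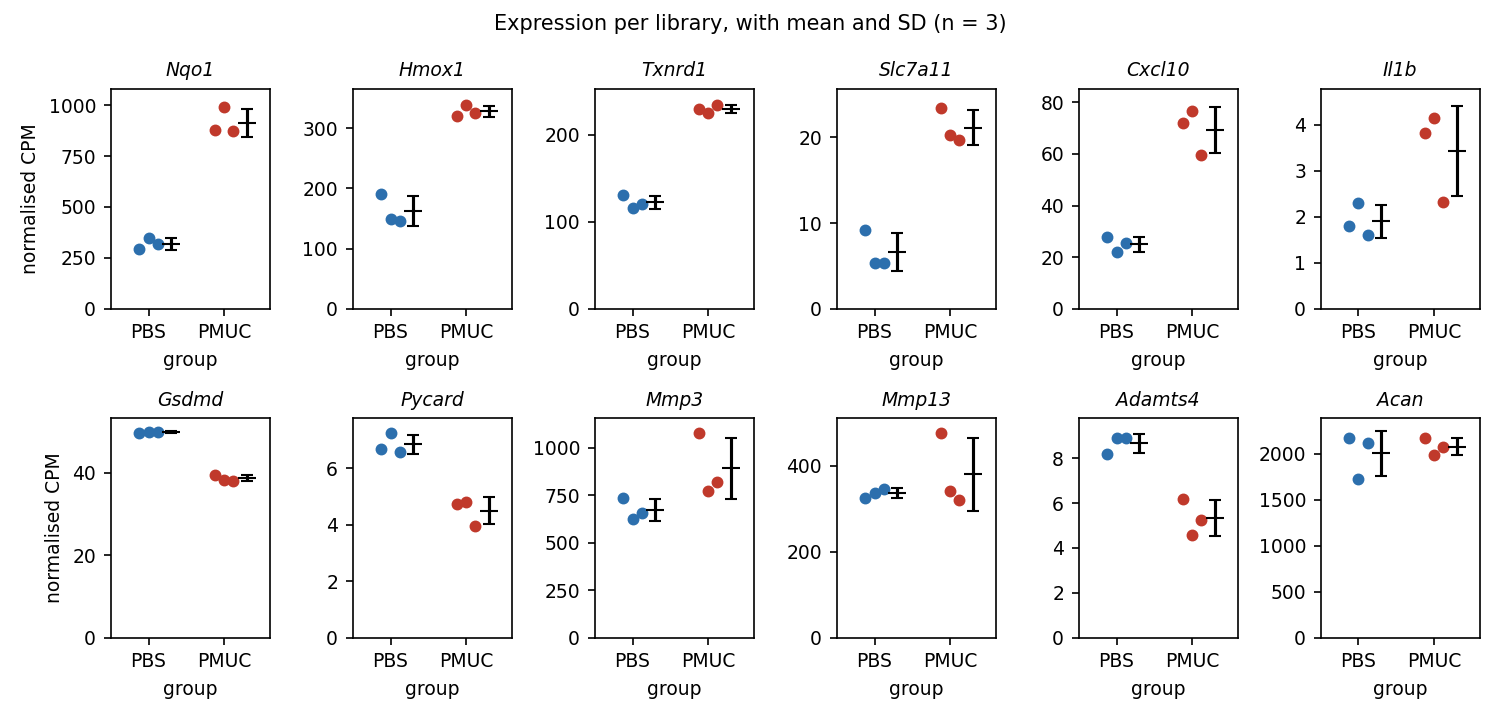
Normalised CPM (vertical axes, starting at 0) of 12 genes in each of the 3 PBS libraries (blue) and 3 PMUC libraries (red), with the mean and SD of each group in black. Nqo1, Hmox1, Txnrd1, Slc7a11 and Cxcl10 were higher in all 3 PMUC libraries than in all 3 PBS libraries, Gsdmd, Pycard and Adamts4 were lower, and the groups overlapped for Mmp13 and Acan.

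The genes of cartilage matrix and chondrocyte identity showed 1 call among 18 tested members (also 1 when adjusted over the list alone): Col11a1, a collagen chain of cartilage, was lower in PMUC (151 ± 3.51 against 128 ± 6.45 CPM, edgeR adjusted p = 0.0248). Acan, which encodes aggrecan, stood at 2006 ± 242 CPM in PBS and 2079 ± 95.04 CPM in PMUC (log2 fold change 0.05, SE 0.08, edgeR adjusted p = 0.745). The log2 fold changes of Sox9 (-0.05, SE 0.08, edgeR adjusted p = 0.748) and Prg4, the lubricin gene (-0.28, SE 0.34, edgeR adjusted p = 0.650), did not pass either. Col2a1, the gene of the main cartilage collagen, had 0 to 2 counts in every library, which is below the limit of 3 counts, so no comparison was possible. Whether this reflects the state of the cells or the annotation used for counting was not settled. Col10a1 had 1 to 3 counts and was not tested. The camera adjusted p of the list was 0.701, its median was 0.05 and its mean lay just below 0. The edgeR adjusted p of Col11a1 was 0.104, 0.142 and 0.142 without PBS replicate 3 and PMUC replicates 2 and 3.

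Genes of hypertrophy and ossification had 2 falls and 0 rises among 14 tested members (3 and 0 when adjusted over the list alone), with 4 falls without PBS replicate 1 and 1 without PBS replicate 3 or any 1 of the PMUC libraries. The list had a camera adjusted p of 0.0793, which was 0.0254 and 0.0439 without PBS replicate 2 and PMUC replicate 2. Pth1r, the parathyroid hormone receptor gene, fell from 11.7 ± 0.35 to 7.76 ± 0.53 CPM. Dlx5 fell from 0.54 ± 0.10 to 0.16 ± 0.02 CPM. The edgeR adjusted p of Dlx5 was between 0.0564 and 0.103 without PBS replicate 2, PBS replicate 3 or any 1 of the PMUC libraries. Runx2 (log2 fold change -0.14, edgeR adjusted p = 0.549) did not pass, and its edgeR adjusted p was 0.0326 without PBS replicate 2. Among 22 fibroblast and contractile genes, Acta2 and Cnn1 fell (log2 fold change -0.30 and -0.34) and 0 rose (3 and 0 when adjusted over the list alone), with a camera adjusted p of 0.605. Without PBS replicate 1, 1 member rose and 6 fell, without PMUC replicate 2, 1 fell, and 0 fell without PBS replicate 3 or PMUC replicates 1 or 3. Col1a1 had a log2 fold change of -0.00 (SE 0.10, edgeR adjusted p = 0.981). Its level was high in both groups, at 11560 ± 1623 CPM in PBS and 11520 ± 944 CPM in PMUC, while Col2a1 had 0 to 2 counts per library. Acta2 stood at 2447 ± 259 CPM in PBS and 1986 ± 52.6 CPM in PMUC. The edgeR adjusted p of Acta2 was 0.137, 0.104, 0.0935 and 0.152 without PBS replicate 3 and PMUC replicates 1, 2 and 3, and that of Cnn1 was 0.0804, 0.0998 and 0.0845 without PBS replicate 3 and PMUC replicates 1 and 3.

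Of 23 tested genes of the unfolded protein and integrated stress response, 0 rose and 5 fell, also when adjusted over the list alone. The median log2 fold change was -0.08, with a camera adjusted p of 0.0491, and of 0.813 with an estimated correlation. The fry adjusted p was 0.0642. Of the 5 that fell, 3 encode enzymes of amino acid synthesis: Asns makes asparagine (33.96 ± 1.12 to 23.9 ± 0.36 CPM), while Psat1 (17.5 ± 1.77 to 11.6 ± 0.10 CPM) and Phgdh (9.96 ± 1.81 to 6.402 ± 0.14 CPM) make serine. Herpud1 and Creld2, genes of endoplasmic reticulum proteins, were the others (log2 fold change -0.29 and -0.30), Creld2 being named after its value was seen. The camera adjusted p of the list was 0.113 without PBS replicate 1, 0.153 and 0.0772 without PMUC replicates 1 and 3, 0.0529 with named symbols only, and 0.149 with the trend with gene length removed. Without PMUC replicate 3, the edgeR adjusted p of Phgdh was 0.0628, and that of Herpud1 was 0.0911, 0.0897 and 0.0761 without PMUC replicates 1, 2 and 3. The number that fell was 3, 3 and 2 without those libraries, and 2 rose without PBS replicate 1.

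With all 6 libraries, TMM factors and the default filter, the remaining pathway lists gave no call by camera. Among 26 TGF-beta and BMP genes, 1 rose and 4 fell (2 and 5 when adjusted over the list alone, camera adjusted p = 0.668), the lowest p being that of Smad6, an inhibitor of BMP signalling (29.2 ± 1.15 to 21.5 ± 0.33 CPM, edgeR adjusted p = 0.00293). The number that fell was 1 without PBS replicate 3 or in the FPKM fit with no filter and 2 without any 1 of the PMUC libraries. The number that rose was 2 without PBS replicate 1, with no count filter and with DESeq2, and 0 without PBS replicates 2 or 3 or PMUC replicates 1 or 3 and in the FPKM fits. Among 28 mechanosensing genes and YAP targets, 3 rose and 2 fell, also over the list alone (camera adjusted p = 0.4999), with Ccn2, a connective tissue growth factor gene, falling from 1610 ± 66.1 to 1180 ± 9.37 CPM. Without PBS replicate 2 or 3, with upper-quartile factors or with the filtered FPKM fits 1 rose, without any 1 of the PMUC libraries or with log2(FPKM + 1) and no filter 0 rose, and with no count filter 5 rose. In that unfiltered FPKM fit, and without PBS replicate 3 or any 1 of the PMUC libraries, 1 fell. Of 36 extracellular vesicle genes, 1 rose and 1 fell, also over the list alone (camera adjusted p = 0.668). Without PBS replicate 1, 3 rose and 5 fell, and without PBS replicate 2, 2 rose. With all 6 libraries they were Anxa2, an annexin gene, with a log2 fold change of 0.23, and Flot2, a flotillin gene, with -0.32. Of 16 hyaluronan genes, 2 rose and 0 fell (2 and 2 when adjusted over the list alone, camera adjusted p = 0.701). Has2, a hyaluronan synthase gene, rose by 0.34 and Cd44, a hyaluronan receptor gene, by 0.27, while the list's median of -0.01 and mean of -0.04 were below 0 and its camera direction was upward. Without PBS replicate 3 or any 1 of the PMUC libraries, the edgeR adjusted p ran from 0.0667 to 0.172 for Anxa2 and from 0.0618 to 0.0888 for Cd44. That of Has2 was 0.0670 and 0.0889 without PBS replicate 3 and PMUC replicate 3, and that of Flot2 was 0.0534 without PMUC replicate 3.

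Of 24 autophagy genes, 1 rose and 0 fell, also over the list alone (camera adjusted p = 0.668): the cargo receptor gene Sqstm1, from 451 ± 9.92 to 563 ± 4.34 CPM, with 3 rises without PBS replicate 1. Of 16 heat shock genes, 2 rose and 0 fell (4 and 0 when adjusted over the list alone), Bag3 and Hsp90aa1, with a camera adjusted p of 0.119, of 0.0323 without PBS replicate 2 and of 0.0474 with the trend with gene length removed. Without PBS replicate 3 or any 1 of the PMUC libraries, the edgeR adjusted p ran from 0.0525 to 0.0886 for Bag3 and from 0.0856 to 0.135 for Hsp90aa1. Of 31 cell cycle genes, 1 rose and 2 fell (2 and 2 when adjusted over the list alone), with Tyms, the thymidylate synthase gene, falling from 38.9 ± 2.09 to 27.5 ± 1.53 CPM. The camera adjusted p of this list was 0.0793, and 0.00546, 0.0407 and 0.0197 without PBS replicate 1, PMUC replicate 1 and PMUC replicate 2. It was also under 0.05 in 5 other settings: 0.0485 with no count filter, 0.0242 with CPM of at least 5, 0.0329 with log2(FPKM + 1), 0.0391 with log2(FPKM + 0.1) and 0.0326 with log2(FPKM + 1) and no filter. The number that fell was 4 without PBS replicate 1, 5 with no count filter, and 1 without PBS replicate 3, PMUC replicate 2 or PMUC replicate 3 or with log2(FPKM + 1) and no filter. The number that rose was 2 without PBS replicate 2 or with no count filter, and 0 without PMUC replicates 1 or 2, with log2(FPKM + 0.1) or with log2(FPKM + 1) and no filter. Of 27 genes of cholesterol and fatty acid synthesis, 1 rose and 1 fell, also over the list alone (camera adjusted p = 0.668). Without PBS replicate 1, 2 rose and 4 fell. Elovl6, a fatty acid elongase gene, fell (log2 fold change -0.51, edgeR adjusted p = 0.0261). Its edgeR adjusted p was 0.134, 0.0713 and 0.128 without PBS replicate 3, PMUC replicate 1 and PMUC replicate 3. Of 19 senescence and p53 genes, 0 passed (0 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.0862, and 0.0141 with log2(FPKM + 1) and no filter), the lowest edgeR adjusted p being 0.0555 for Cdkn2a, a cell cycle inhibitor gene, which was 0.00582 without PBS replicate 1. With upper-quartile factors, no count filter, DESeq2, log2(FPKM + 1) and log2(FPKM + 0.1) the adjusted p of Cdkn2a was 0.0459, 0.00513, 0.0297, 0.0385 and 0.0388. Over the left-out libraries, 0 to 1 members of the senescence list rose and 0 to 2 fell.

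Few markers of other cell types passed the edgeR threshold. Of the macrophage and leukocyte markers 3 were expressed well enough to be tested and 0 passed (camera adjusted p = 0.939), and Cd14 stood at 52.6 ± 1.27 CPM in PBS and 49.7 ± 4.47 CPM in PMUC. The camera adjusted p was 0.701 for 6 osteoclast markers, 0.668 for 5 osteoblast markers, 0.605 for 12 synovial fibroblast markers, 0.701 for 6 skeletal muscle markers and 0.605 for 5 adipocyte markers, with 0 members past the edgeR threshold in each. When adjusted over the list alone, 2 synovial fibroblast markers rose and 4 fell, and 0 members of the other 4 lists passed. Without PBS replicate 1, 2 synovial fibroblast markers fell and 1 muscle marker rose. By fry's test for change in either direction the adjusted p was 0.000933 for the synovial fibroblast markers, 0.00206 for the osteoblast markers, 0.0418 for the adipocyte markers and 0.000279 for endothelial and mural markers. Among 7 endothelial and mural markers 1 rose, also over the list alone, Abcc9, a subunit gene of a potassium channel (79.2 ± 7.81 to 125 ± 4.99 CPM, camera adjusted p of the list = 0.699). None of the erythroid markers reached the level for testing, so 0 were tested.

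Terms in the deposited annotation were tested among the called genes. Of 4810 tests of terms in both directions, 23 terms were enriched among genes that rose and 4 among genes that fell at an adjusted p under 0.05 by Fisher's exact test. Among genes that rose, glycolysis and gluconeogenesis held 12 genes where 2.18 were expected by chance (adjusted p = 0.00142). Ferroptosis held 10 against 1.75 (adjusted p = 0.00352), TNF signalling 15 against 4.06 (adjusted p = 0.00466), glutathione metabolism 11 against 2.26 (adjusted p = 0.00468) and cytochrome P450 metabolism of xenobiotics 9 against 1.58 (adjusted p = 0.00566). The glycolysis count includes Aldh3a1, Adh7 and the unnamed loci LOC100362738 and RGD1562690. The ferroptosis count includes the ferritin genes Fth1 and Ftl1 and the unnamed locus LOC100362384, and may include more unnamed loci. The 5 genes counted for the term autolysosome were Fth1, Ftl1 and the unnamed loci LOC100362384, LOC100360087 and LOC100359668. Fisher's exact test counts each locus as a separate gene, and whether these loci share reads with named genes was not tested. Among genes that fell, extracellular matrix organization held 16 against 3.84 (adjusted p = 0.00142), including Kazald1, Olfml2b, Col8a2 and Adamts4. With the genes changed by more than 2-fold in their place, 11 terms were enriched among genes that rose and 0 among genes that fell.

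The groups separated along the first principal component, which held 38.8% of the variance. All 3 PMUC libraries lay between 8.50 and 9.59 on it, while the PBS libraries were spread from -12.9 for replicate 2 to -4.38 for replicate 1. Spearman correlations across genes were 0.998 between PMUC libraries, 0.995 to 0.997 between PBS libraries and 0.991 to 0.996 between groups, and genes are not independent replicates. PBS replicate 1 correlated more with PMUC replicates 1, 2 and 3 (0.9962, 0.996 and 0.9963) than with PBS replicate 2 (0.9946). Its highest correlation was with PBS replicate 3 (0.9972). Fold changes also followed the gene length implied by the tables (Spearman rho across tested genes 0.24). The libraries differed in this: each library's deviation from the gene mean had a Spearman rho with length of -0.43 in PBS replicate 2 and 0.33 in PMUC replicate 1, against -0.01 to 0.18 in the other 4. The median log2 fold change was -0.07 in the 4538 shortest genes, where 105 rose and 196 fell, and 0.05 in the 4538 longest, where 220 rose and 134 fell. With each library's trend with length removed, 722 genes were higher and 734 lower.

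**Figure D4:**
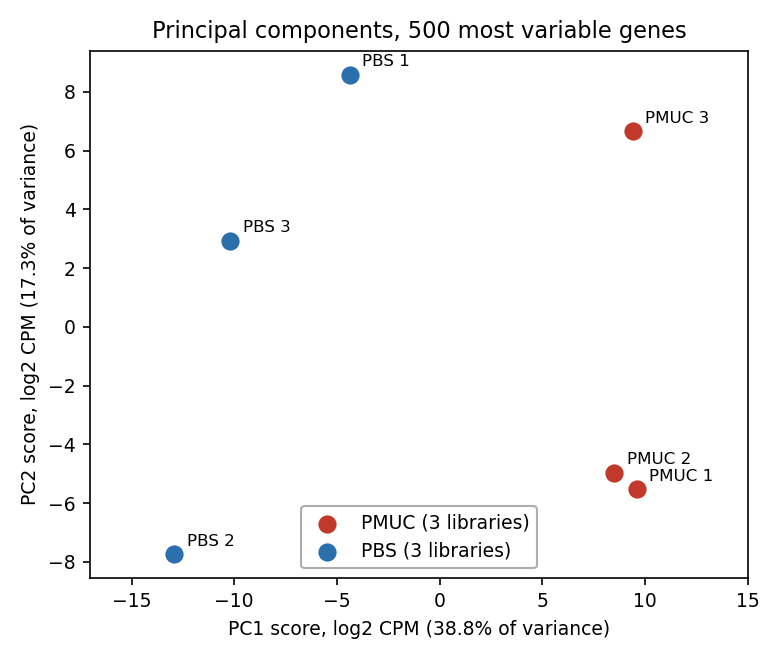
Scores of the 6 libraries on the first and second principal components of the 500 most variable genes (log2 CPM), with 38.8% of the variance on the horizontal and 17.3% on the vertical axis. The PMUC libraries (red) lie between 8.50 and 9.59 on the horizontal axis and the PBS libraries (blue) between -12.9 and -4.38.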

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

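The length-trend fit was chosen after seeing the data, and the other alternatives before. Of the 73 named genes past the threshold, 30 kept their direction and call in every alternative that gave them a value, 12 settings and 6 left-out libraries, and 43 did not in at least 1. The named genes that reversed had not passed the threshold. The oxidative stress list rose in every alternative, with 10 to 20 members past the threshold, and lost its call only with an estimated correlation.

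Genes higher and lower in PMUC numbered 822 and 947 with no count filter, of which 50 and 71 changed by more than 2-fold. They numbered 265 higher with log2(FPKM + 1), 263 with log2(FPKM + 0.1), and 81 higher and 107 lower with log2(FPKM + 1) and no filter. Changes of more than 2-fold in those 3 fits numbered 12 and 1, 19 and 5, and 11 and 1, and 12 and 2 with CPM of at least 5, where fewer genes were tested. With the length trend removed 722 were higher. Leaving out 1 library gave 168 to 910 higher and 121 to 919 lower, 26 to 47 and 10 to 58 of them by more than 2-fold, and the cause was not tested except for PBS replicate 1.

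With the replicate number as a block, 950 were higher and 938 lower, of which 38 and 54 changed by more than 2-fold, and the unfolded protein list had an adjusted p of 0.0639. Same-numbered libraries deviated together with correlations of 0.04, 0.13 and -0.06, and not every library correlated best with its own number, so the numbers were not taken to pair samples.

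The camera direction of the matrix-degrading list was downward at an adjusted p of 0.871 with CPM of at least 5, 0.913, 0.876 and 0.934 in the FPKM fits, and 0.925 to 0.960 without PBS replicate 2 or PMUC replicates 1 or 2. Over all left-out libraries its adjusted p ran from 0.768 to 0.96. That of the cartilage list was downward at 0.966 with the length trend removed and at 0.684 without PBS replicate 2, and ran from 0.428 to 0.95 over the left-out libraries. With named symbols only, the unfolded protein and oxidative phosphorylation lists both had 0.0529, which left 3 calls among the lists other than cartilage, matrix-degrading and pyroptosis. With the length trend removed these had 0.149 and 0.715, and over the left-out libraries they ran from 0.0159 to 0.153 and 0.00509 to 0.661, with 3 to 7 such calls, these 2 lists included where they passed. With an estimated correlation 0 were called, at 0.268 for oxidative stress and 0.813 for the inflammatory, unfolded protein, glycolysis and oxidative phosphorylation lists. The genes above 2-fold gave 11 enriched terms in all. Apart from the fit with the length trend removed, the cause of these changes was not tested. The oxidative phosphorylation list had a camera adjusted p of 0.661 and 0.357 without PBS replicate 2 and PMUC replicate 1. These libraries had the strongest trends with length (Spearman rho -0.43 and 0.33). That trend may therefore account for the list's downward call, which was also lost, at 0.0772, without PMUC replicate 3.

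The Acan log2 fold change was -0.00589 with the length trend removed, and ran from -0.0447 without PBS replicate 2 to 0.117 over the left-out libraries. The Col1a1 log2 fold change was 0.00292 with limma voom and 0.00222 with the block, and ran from -0.115 to 0.0822 without PBS replicates 2 and 3. The Casp1 log2 fold change ran from -0.516 without PBS replicate 1 to 0.557 without PBS replicate 3, the Cd68 log2 fold change from -0.172 to 0.348 without PMUC replicates 1 and 2, the Mmp13 log2 fold change from -0.0137 to 0.290 without PMUC replicates 1 and 3, and the Prg4 log2 fold change from -0.475 without PMUC replicate 1 to 0.0427 without PBS replicate 1. Depth limits genes such as Casp1, with 0 to 13 counts per library.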

Other observations

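The tests of shared reads, of single PBS libraries, of a wrong label or mixed sample, of a general interferon response and of other splits of the libraries were chosen after the result was seen, as were the gene lists and genes below. A set of 20 further NRF2 targets that are not in the oxidative stress list held 10 genes that rose and 0 that fell. Among them, Gstp1, a glutathione S-transferase gene, went from 203 ± 24.9 to 331 ± 14.96 CPM (edgeR adjusted p = 0.000341), and Pgd, an enzyme gene of the pentose phosphate pathway, from 595 ± 17.3 to 838 ± 36.0 CPM (edgeR adjusted p = 0.000442). Taldo1 and Tkt, of the same pathway, rose by 0.44 and 0.38 on the log2 scale, and Slc48a1, a heme transporter gene, by 0.45.

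Of genes known to be induced through the aryl hydrocarbon receptor, a sensor of aromatic compounds, 4 are named here, and no list of such genes was tested. Cyp1a1 had 64, 64 and 76 counts in the PMUC libraries and 21, 7 and 5 counts in the PBS libraries (log2 fold change 2.70, edgeR adjusted p = 0.00165). Ahrr, the receptor's repressor gene, went from 33.0 ± 0.98 to 52.3 ± 3.21 CPM. Cyp1b1 went from 2236 ± 142 to 3869 ± 66.5 CPM (edgeR adjusted p = 2.30e-05) and Tiparp from 65.9 ± 4.07 to 115 ± 1.94 CPM (edgeR adjusted p = 1.42e-05).

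The rise of the oxidative stress list was not limited to genes with close relatives, since the members without them had a median log2 fold change of 0.69 and 12 of 14 passed the threshold. At least 13 members passed whichever PBS library was left out, and 19 passed with the trend with gene length removed, which argues against both as the whole cause. The further NRF2 targets had a median log2 fold change of 0.24 (camera p = 5.70e-06, p = 0.0518 with an estimated correlation, fry p = 0.00309), in line with a wider NRF2 response. Both of 2 receptor targets tested, Cyp1a1 and Ahrr, were higher in all 3 PMUC than all 3 PBS libraries, so an aryl hydrocarbon receptor response may also contribute, and Nqo1 and Aldh3a1 are known targets of both. These are hypotheses found and tested on the same libraries.

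The rise of Cxcl10, Ccl5, Isg15, Acod1 and Gbp4, summed at 41.9 ± 5.69 CPM in PBS and 108 ± 9.74 CPM in PMUC, was weighed against RNA from leukocytes. The summed CPM of 10 leukocyte transcripts changed by -4.33% of that rise, or 0.119% without Cd14, so leukocyte RNA would have to lack its abundant transcripts. The 21 other members of the interferon list had a median log2 fold change of -0.145 and an upper quartile of 0.18. Their median argues against a general rise across these 21 members, of which Usp18 rose and Psmb8 and Irf7 fell. Genes outside the list were not weighed. The upper quartile lay below the 1.09 of the smallest of the 5 rises, and stayed below it without each library in turn. Since the 5 genes were picked after their rises were seen, that comparison was largely fixed in advance and no conclusion is drawn from it. What raised these 5 genes stays open.

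The number of genes past the threshold rose from 953 to 1829 without PBS replicate 1. That library lay between the groups, at a median of 0.52 on a CPM scale from PMUC (0) to the other PBS libraries (1) over the genes called without it, and nearer the other PBS libraries at 52.3% of them, against 86.2% to 97.9% nearer their own group for the other 5 libraries. Across tested genes its Spearman correlation was 0.9946 with PBS replicate 2, 0.996 to 0.9963 with the PMUC libraries and 0.9972 with PBS replicate 3. A PMUC library with a wrong label is argued against, since PBS replicate 1 lay beyond the PMUC libraries on the PBS side at 27.5% of the genes called without it. Each other library was tested likewise on the genes called without it. The PMUC libraries gave 0.346% to 1.76%, and PBS replicates 2 and 3 gave 73.75% and 75%. A mixture with PMUC material needs 1 share for all genes. The median position of PBS replicate 1 was 0.93 (quartiles 0.77 and 1.15) over 16 oxidative stress list members called without it, which argues against a large share of PMUC material in all genes. A small share cannot be excluded. The genes were chosen from the other 5 libraries, which can place PBS replicate 1 too near PMUC, most at small changes. The 0.93 and the 0.52 over all called genes therefore need not stand for different shares. Over genes changed by more than 2-fold the median position of PBS replicate 1 was 0.79 for 45 higher and 0.53 for 53 lower genes, the latter near the median of all called genes. The depth of PBS replicate 2 is argued against, since the ratio of the counts was 1.81 after thinning all libraries to one total, while with the trend with gene length removed it was 1.495, barely under the bound of 1.5 set beforehand, so that trend may account for part of the change and the rest stays open. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 953, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.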
